A study of Mus musculus with 6 samples.

How the data were processed

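Total RNA was profiled in 3 subsets of mouse dorsal root ganglion (DRG) cells sorted by flow cytometry, with 2 libraries per subset and 6 in all. The animals were heterozygous for an mCherry reporter at the locus of GINIP, a protein that binds inhibitory G protein subunits, and cells were also stained with isolectin B4 (IB4), which binds many non-peptidergic nociceptors. DP cells were positive for both and are described in the labels as Mrgprd-expressing neurons, C-LTMR cells (C-fibre low-threshold mechanoreceptors) were positive for GINIP only, and DN cells were negative for both and hold the remaining cells. Per the labels' protocols, cells were sorted into lysis buffer, 50 ng of RNA was amplified with an amino allyl in vitro transcription kit, and TruSeq RNA libraries were sequenced on an Illumina HiSeq instrument. The labels give replicate numbers but do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

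Per the submitters' processing notes, the authors used CASAVA 1.8.2, edgeR 2.6.2 and the mouse build GRCm38 (mm10). Which tool made which step, the aligner settings, the gene annotation and the use of strand are not given in the sources used here. The deposited RPKM table lists 23029 genes, with 19 repeated symbols, as reads per kilobase of gene and per M reads of the library. The second deposited table, whose unit is a TMM-normalized count (a normalized signal brought to a common library size, not a whole number), lists 6620 genes. Each of its genes reached 892 or more in both libraries of at least 1 subset, so genes below that level in all 3 subsets are not in the comparisons. Gene symbols, Entrez IDs and GRCm38 coordinates were used as the files give them. Of the RPKM table's genes, 22954 (99.7%) had their Entrez ID in a RefSeq gene table of the same build, and 99.5% of these overlapped its position.

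Depth was not stated. Low RPKM values fall on steps that depend on gene length and on the number of reads, and from these steps the libraries were estimated to hold 42.2 and 38.5 M reads (DP), 34.3 and 32.0 M (C-LTMR) and 39.4 and 32.0 M (DN). With the estimated lengths, between 28.3% and 31.3% of low values lay within 0.05 of a whole read, against 10% by chance. Whole reads could therefore not be recovered and no count model was fitted. A value under about 3 normalized counts is at the floor that 3 reads set, and it is given as a level without a fold change. Floors cover counting error only, since the RNA was amplified and reads carry no molecular identifiers.

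Normalized counts were taken as log2(value + 1), and a fold change is on that scale, which understates the change of low genes. A filter of at least 10 in at least 2 libraries removed 0 genes. All 6 libraries entered a single limma 3.58.1 fit in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), because 2 libraries per subset leave only 3 residual degrees of freedom. The median prior degrees of freedom were 3.26. A gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05 and an absolute log2 fold change of at least 1. Adjusted p-values of genes come from this fit unless an alternative or the RPKM table is named. Genes called higher, or lower, in a subset against both others form its enriched, or depleted, set. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for depth estimates and plots.

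Before the data were examined, 29 gene lists were fixed: markers of non-peptidergic Mrgprd nociceptors, C-LTMRs, myelinated mechanoreceptors and proprioceptors, peptidergic nociceptors and thermoreceptors, and itch-related neurons, pan-sensory-neuron genes, markers of satellite glia and Schwann cells, of endothelial cells, pericytes and fibroblasts, and of immune cells, red blood cell genes, immediate early, stress and injury genes, neuropeptide and hormone precursors, voltage-gated potassium, sodium and calcium channels, leak (Kcnk) and inward rectifier (Kcnj) potassium channels, TRP channels, ionotropic purinergic, acid-sensing, HCN and mechanosensitive channels, ionotropic and metabotropic GABA, glycine, glutamate and acetylcholine receptors, Mas-related receptors, amine, opioid, prostaglandin and somatostatin receptors, axon guidance genes, cadherins, neurotrophic factor receptors, sensory neuron transcription factors, RGS and G protein subunit genes, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation subunits, and mitochondrially encoded genes. The list of purinergic, acid-sensing, HCN and mechanosensitive channels also took anoctamin (Ano) genes. Some genes were in several lists, so list results are not separate evidence. Gfra2, Ret and Runx1 were in the lists of Mrgprd nociceptors and of C-LTMRs. Tac1, Calca, Calcb, Gal and Adcyap1 were among the peptidergic markers and the neuropeptide precursors, and Gal also among the immediate early genes. The 24 lists with at least 5 measured members were tested with limma's camera (two-sided, preset inter-gene correlation of 0.01), with BH adjustment over 72 tests, and again with an estimated correlation, which rests on 3 residual degrees of freedom. Of the 72 tests, 27 passed with the preset correlation and 0 with the estimated one, where 6 were under 0.05 before adjustment.

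The genes named were set by a rule also fixed beforehand. It took the 8 largest log2 fold changes per direction among called genes of each comparison with a mean of at least 50 in the higher subset, both libraries of one subset above both of the other, and a symbol that is not a predicted gene model. It also took the 5 genes of each enriched set with the largest smaller-of-both fold change, and the reporter gene with the subset markers Mrgprd, Th, Slc17a8 and Fam19a4. Last, it took up to 4 called members of each list with the largest fold change, or the first 2 measured members where none was called. Genes outside the rule are named as such, and some genes that the rule took are not reported here.

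The replicate numbers were checked for pairing before any calls were compared. The deviations of replicate 2 from replicate 1 correlated across genes with a Pearson r of 0.534 between DP and C-LTMR, 0.126 between DP and DN and 0.363 between C-LTMR and DN (Spearman 0.598, 0.0639 and 0.2). Genes are not independent replicates, and the labels share replicate numbers without saying what a number stands for, so the pairing is a hint from the data. A fit with a replicate block was an alternative. Other alternatives fixed at the same time were pseudocounts of 0.5 and 5, no filter, a filter of at least 50, the RPKM table (log2(RPKM + 0.1), RPKM of at least 0.3 in at least 2 libraries), quantile normalization, median-of-ratios rescaling, only the libraries compared, each library left out, no fold criterion, and limma's treat test. Rescaling to the pan-sensory-neuron genes and the RPKM table limited to the 6620 genes were added after the data were seen, as was an overlap with separate DN libraries for DP and for C-LTMR. In the overlap of comparisons that share the DN libraries, 100 draws of unchanged groups against simulated DN libraries gave the correlation and covariance with no effect.

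The fit was tested on simulated data of 6620 genes with 200 changed per comparison, 50 at each fold. At 3-fold and 4-fold, 100% were called in each comparison. At 2-fold, the share was 50% for DP vs C-LTMR, 36% for DP vs DN and 54% for C-LTMR vs DN, and at 1.5-fold it was 0% in each, as the fold criterion requires. Of 6420 unchanged genes, 0 were called in any comparison, and 1, 7 and 12 were under the adjusted p threshold alone in limma. All genes of a subset had the same simulated spread, and their levels were means over all 6 libraries. These shares therefore do not carry over to genes with a larger spread or with a subset near the floor. A simulated list of 20 genes at 2-fold gave a camera p of 5.71e-133 with the preset and 0.000132 with the estimated correlation, and 7 and 1 of 200 unchanged lists were under 0.05. Genes were drawn independently here, so this cannot show how the preset correlation behaves in lists whose members correlate. Estimated correlations in the real lists reached 0.73, for the ribosomal proteins.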

Results

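Gene expression was measured in 3 subsets of cells sorted from mouse dorsal root ganglia, the ganglia that hold the cell bodies of the body's sensory neurons. DP cells (IB4+GINIP+) are the neurons that express the receptor Mrgprd and end in the skin as free nerve endings. C-LTMR cells (IB4-GINIP+) are unmyelinated low-threshold mechanoreceptors, and DN cells (IB4-GINIP-) are what remains. Each subset had 2 libraries, so n = 2 for every mean ± SD given here. Values are the authors' TMM-normalized counts of 6620 genes, which summed to between 29283094 and 31262583 per library. Depth estimated from the RPKM values lay between 32.0 and 42.2 M reads per library. Replicates correlated across genes with r = 0.9937 in DP, 0.9897 in C-LTMR and 0.9732 in DN on the log2 scale. Between subsets, r was 0.855 to 0.873 for DP and C-LTMR, 0.559 to 0.627 for DP and DN, and 0.483 to 0.589 for C-LTMR and DN.

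The reporter gene and marker genes of the subsets, which the sort did not use, followed the sort labels. The gene of GINIP (listed as N28178, Entrez 230085, chromosome 4, 42917251 to 42941607) was at 15519 ± 640 in DP, 17401 ± 768 in C-LTMR and 2012 ± 349 in DN. It was higher than in DN in both sorted GINIP+ subsets (log2 fold change 2.96 and 3.12, limma BH-adjusted p = 1.27e-05 and 1.2e-05). DP and C-LTMR did not pass the test against each other for this gene (log2 fold change -0.17, SE 0.125, limma BH-adjusted p = 0.358). Mrgprd (Entrez 211578, chromosome 7, 145314835 to 145324059) was at 28264 ± 4329 in DP against 183 ± 53.4 in C-LTMR and 74.3 ± 51.5 in DN. Th, the rate-limiting enzyme of catecholamine synthesis (Entrez 21823, chromosome 7, 142892776 to 142899966), was at 63722 ± 1127 in C-LTMR, 3543 ± 551 in DP and 1468 ± 740 in DN. The vesicular glutamate transporter gene Slc17a8 (Entrez 216227, chromosome 10, 89574020 to 89621249) was at 2843 ± 239 in C-LTMR, 197 ± 20.2 in DP and 61.1 ± 33.7 in DN. Fam19a4, which encodes a secreted protein (Entrez 320701, chromosome 6, 96831209 to 97060411), was at 15912 ± 1644, 1830 ± 170 and 26.5 ± 5.22 in the same order. All of these differences were called except where said, but some of the smaller ones lost their call when a library was left out. Such a loss need not mean a smaller change, since fewer libraries then measure the spread. Without either DP library the log2 fold change of Mrgprd in C-LTMR over DN stayed at 1.45. Th in DP over DN (log2 fold change 1.36, limma BH-adjusted p = 0.0108) fell below the fold criterion without DN replicate 2 (0.82) and lost its call without DP replicate 2 (limma BH-adjusted p = 0.0549). Mrgprd in C-LTMR over DN (1.45, limma BH-adjusted p = 0.0392) lost its call without DN replicate 1 (0.69, adjusted p = 0.0764) and without DP replicate 1 (0.0642), without DP replicate 2 (0.0648), without C-LTMR replicate 1 (0.0638) and without C-LTMR replicate 2 (0.173), when rescaled to pan-sensory-neuron genes (0.14), in the fit of only the 4 libraries compared (0.115) and with limma treat (0.909).

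**Figure D1:**
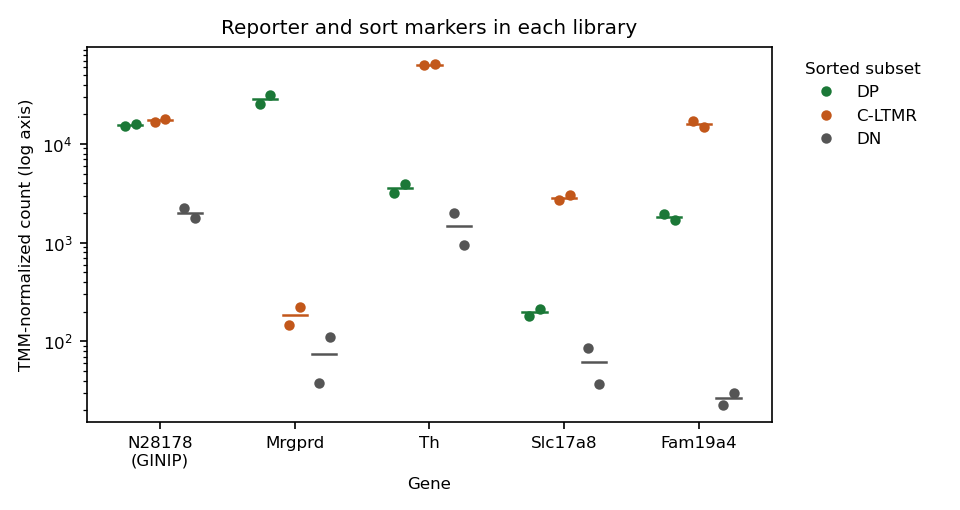
Normalized counts of the reporter gene (N28178, GINIP) and of 4 marker genes of the subsets, which were not used for the sort, in each library. The axis is a log axis, with points for libraries and bars for the mean of the 2 libraries of a subset. Mrgprd lies at 28264 in DP and Th at 63722 in C-LTMR, while N28178 is at 15519 and 17401 in the GINIP+ subsets and at 2012 in DN.

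DP and C-LTMR, the GINIP+ subsets that the IB4 gate separates, differed in marker genes of the known neuron types and in some genes of myeloid blood cells. Markers of Mrgprd nociceptors that were higher in DP included the angiotensin receptor gene Agtr1a (3598 ± 171 against 15.5 ± 5.79 in C-LTMR), the lysophosphatidic acid receptor gene Lpar3 (17161 ± 427 against 219 ± 0.596) and Prkcq, a protein kinase C gene (13556 ± 306 against 202 ± 23.2). In C-LTMR, Th was 18-fold higher than in DP, the zinc finger gene Zfp521 17.5-fold (8830 ± 946 against 504 ± 103) and Cacna1i, a T-type calcium channel gene, 16.6-fold (4269 ± 913 against 257 ± 65.1). Of genes known from neutrophils or macrophages, S100a9, Ngp and Lyz2 were at 1926 ± 147, 1197 ± 41.3 and 1237 ± 137 in DP and at 1.08 ± 1.51, 2.14 ± 1.55 and 4.7 ± 4.93 in C-LTMR. Cd14, another immune marker, was at 382 ± 60.3 in DP and 326 ± 158 in C-LTMR and was not called, and the list of 3 measured immune markers was too short for a test.

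In all, 843 of 6620 genes were called between DP and C-LTMR (12.7%), 405 higher in DP and 438 higher in C-LTMR, with a median absolute log2 fold change of 1.66. The largest changes toward DP, after S100a9 and Ngp (which were at the floor in C-LTMR), were Lyz2 (Entrez 17105, log2 fold change 8.09), Otoa (Entrez 246190, chromosome 7, 121083438 to 121163089; 8.01), Agtr1a (Entrez 11607, chromosome 13, 30336356 to 30382867; 7.82) and Mrgprd (7.29). Next came Lpar3 (Entrez 65086, chromosome 3, 146220961 to 146286214; 6.29) and Prkcq (Entrez 18761, chromosome 2, 11172382 to 11301226; 6.07). Their SE ran from 0.226 for Prkcq to 0.74 for Otoa, and limma BH-adjusted p from 2.86e-05 for Lpar3 to 0.000435 for Otoa. The largest changes toward C-LTMR were led by Ceacam10 (Entrez 26366, chromosome 7, 24777204 to 24784655; log2 fold change -4.24), Osta, a subunit gene of an organic solute transporter (Entrez 106407; -4.18), Th (-4.18), Zfp521 (Entrez 225207, chromosome 18, 13687014 to 13972733; -4.14). Next came Bmp15, a growth factor gene (Entrez 12155; -4.12), Cacna1i (Entrez 239556, chromosome 15, 80287238 to 80398292; -4.06), Tmem132c (Entrez 208213; -4.03) and C1ql4 (Entrez 239659; -4.01). For these, limma BH-adjusted p ran from 3.73e-05 for Zfp521 to 0.00329 for C1ql4, and C1ql4 lost its call without either C-LTMR library (0.15 without C-LTMR replicate 1 and 0.147 without C-LTMR replicate 2). The C-LTMR libraries of Lyz2 were at 8.19 and 1.22. With values rescaled to pan-sensory-neuron genes, 650 genes were higher and 306 lower in DP (68% higher, against 48%), with a shift of the median of all genes from 0.0222 to 0.356.

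Of 21 measured markers of non-peptidergic Mrgprd nociceptors, 16 were higher in DP and 1 was lower (camera BH-adjusted p = 2.97e-07; adjusted p = 0.406 with an estimated correlation). Of 17 C-LTMR markers, 12 were lower in DP and 0 higher (camera BH-adjusted p = 2.07e-06; adjusted p = 0.406 with an estimated correlation). Counts adjusted over the list alone were the same for every list of this comparison except the endothelial list (9 higher and 2 lower) and the sodium channels (1 higher and 6 lower). Among transcription factors, 1 of 18 was higher and 5 were lower, Zfp521, Pou4f2 (637 ± 33.2 against 4765 ± 301) and Etv1 (739 ± 33.7 against 3680 ± 37.8) among the latter, but the list did not pass (camera BH-adjusted p = 0.248). Pou4f3, at 80 ± 0.63 in DP and 22.8 ± 1.72 in C-LTMR, was the member called higher, and its call was lost under quantile normalization (log2 fold change 0.32, limma BH-adjusted p = 0.451).

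Ion channels divided between these subsets. Of 10 measured voltage-gated sodium channel genes, 5 were lower in DP and 1 was higher. Among those lower were Scn1a (192 ± 77.9 against 1612 ± 67.7), the auxiliary subunit gene Scn3b (1107 ± 10.2 against 5774 ± 122) and Scn8a (836 ± 200 against 2985 ± 378). The list passed with camera (BH-adjusted p = 0.0351; adjusted p = 0.788 with an estimated correlation), but not with a replicate block (BH-adjusted p = 0.0541), in the RPKM table with the genes of the TMM-normalized table (0.0504) or without C-LTMR replicate 2 (0.0533). Of 8 TRP channel genes, 3 were higher in DP and 0 lower, among them Trpc6 (2458 ± 97.4 against 410 ± 58.3) and the irritant receptor gene Trpa1 (3055 ± 396 against 695 ± 70.6). This list also passed with camera (BH-adjusted p = 0.0351; adjusted p = 0.58 with an estimated correlation) and not with a replicate block (BH-adjusted p = 0.0622), in the RPKM table (0.0988) or without C-LTMR replicate 2 (0.0576). Among 7 calcium channel genes, Cacna1i, Cacna1h (162 ± 18.3 against 2164 ± 501) and Cacna2d3 (868 ± 10.6 against 3545 ± 325) were lower in DP and 0 were higher (list camera BH-adjusted p = 0.305). Of 15 voltage-gated potassium channel genes, 3 were higher and 5 lower, with Kcnc4 at 1636 ± 105 in DP against 163 ± 11.5 and Kcnh2 at 158 ± 56.5 against 1204 ± 91.8 (list camera BH-adjusted p = 0.248). Of 7 leak and inward rectifier genes, 2 were higher and 2 lower, with Kcnk12 at 1585 ± 6.59 against 148 ± 9.4 (list camera BH-adjusted p = 0.603). Of 15 genes in the list of purinergic, acid-sensing, HCN and mechanosensitive channels, 4 were higher and 4 lower, the anoctamin gene Ano4 among the latter. The ATP receptor gene P2rx3 was at 23060 ± 1415 in DP against 4570 ± 243 (list camera BH-adjusted p = 0.649).

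Signalling genes held members in both directions. Of 31 genes of RGS proteins and G protein subunits, 9 were higher in DP and 4 lower (camera BH-adjusted p = 0.00437; adjusted p = 0.425 with an estimated correlation; 0.0544 with values rescaled to pan-sensory-neuron genes). Gnb4 (10412 ± 517 against 963 ± 178) and Rgs7 (8860 ± 53.9 against 819 ± 79.4) were higher, and Rgs5 (438 ± 15.6 against 5165 ± 140) was lower. Of 14 GABA, glycine, glutamate and acetylcholine receptor genes, 5 were higher and 2 lower, with Chrna6 at 3590 ± 165 in DP against 618 ± 117 and Chrna4 at 99.9 ± 16.8 against 1500 ± 291 (list camera BH-adjusted p = 0.635). Of 5 amine, opioid, prostaglandin and somatostatin receptor genes, 1 was higher and 3 lower, with the serotonin receptor gene Htr1d at 86.8 ± 20.7 against 1193 ± 192 (list camera BH-adjusted p = 0.163). Of 19 axon guidance genes, 2 were higher and 9 lower, with the semaphorin receptor gene Nrp1 at 1223 ± 362 against 17243 ± 3459 and Sema3e at 173 ± 37.8 against 2361 ± 140 (list camera BH-adjusted p = 0.232). Cadherins gave 1 higher and 4 lower of 6, with Cdh10 at 266 ± 27.3 against 1864 ± 199 (list camera BH-adjusted p = 0.245). Neurotrophic factor receptors gave 2 higher and 4 lower of 12, with Ngfr, the p75 receptor gene, at 1094 ± 112 against 7094 ± 585 (list camera BH-adjusted p = 0.403). Neuropeptide precursors gave 4 higher and 1 lower of 11, with Nmb at 22287 ± 1034 against 4387 ± 146 (list camera BH-adjusted p = 0.15; 0.0372 without DP replicate 2). Peptidergic markers gave 4 higher and 3 lower of 12 (camera BH-adjusted p = 0.535), and myelinated neuron markers 0 higher and 4 lower of 9, Ntrk3 and Necab2 among them (camera BH-adjusted p = 0.18).

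Some markers of other cells also differed between DP and C-LTMR. Of 14 endothelial, pericyte and fibroblast markers, 8 were higher in DP and 2 lower (camera BH-adjusted p = 0.0117; adjusted p = 0.747 with an estimated correlation). The members called higher included the smooth muscle actin gene Acta2 (303 ± 120 against 14.4 ± 7.21) and the collagen gene Col3a1 (374 ± 13.3 against 23.6 ± 17.2), while Rgs5 was among those lower. The list did not pass after quantile normalization (BH-adjusted p = 0.174) or when rescaled to pan-sensory-neuron genes (0.1). The log2 fold change of Col3a1 was 3.35 without C-LTMR replicate 1 and 4.91 without C-LTMR replicate 2. Of 18 satellite glia and Schwann cell markers, 2 were higher and 2 lower (camera BH-adjusted p = 0.652), with Mbp at 2564 ± 410 in DP and 12961 ± 1036 in C-LTMR. Of 3 measured immune markers 2 were higher in DP (S100a9 and Lyz2), and of 3 red blood cell genes 3 were lower, Alas2 and Bpgm among them. Bpgm lost its call under quantile normalization (log2 fold change -0.89), rescaled to pan-sensory-neuron genes (-0.71), without DP replicate 1 (-0.996) and without C-LTMR replicate 2 (limma BH-adjusted p = 0.0516). Of 4 itch-related markers Ptgdr and Plcb3 were higher in DP and Mrgpra3 lower, and of 3 Mas-related receptor genes Mrgprd was higher and Mrgpra3 lower. These 4 lists were too short for camera. Immediate early, stress and injury genes gave 9 higher and 0 lower of 22 (camera BH-adjusted p = 5.8e-05; adjusted p = 0.762 with an estimated correlation), among them Gal (1033 ± 253 against 248 ± 2.62) and Sox11 (2854 ± 19.4 against 1186 ± 38.6). Pan-sensory-neuron genes gave 0 higher and 3 lower of 18, with the enolase gene Eno2 at 2906 ± 2.31 against 23865 ± 1238 (camera BH-adjusted p = 0.162; 0.0235 under quantile normalization). Of 51 cytosolic ribosomal protein genes 0 were called, with a median log2 fold change of 0.229 (camera BH-adjusted p = 0.00402; adjusted p = 0.822 with an estimated correlation; 0.248 without C-LTMR replicate 1 and 0.0615 when rescaled to pan-sensory-neuron genes). Of 65 oxidative phosphorylation genes 0 were called (median -0.0645, camera BH-adjusted p = 0.144), but the list passed without C-LTMR replicate 1 (median -0.179, BH-adjusted p = 0.0031) and under quantile normalization (-0.112, BH-adjusted p = 0.021). The table measured 0 mitochondrially encoded genes.

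DP against DN sets the Mrgprd neurons against the cells outside both gates. In DP, the kainate receptor gene Grik1 (Entrez 14805, chromosome 16, 87895897 to 88290258) was at 37714 ± 2928 against 209 ± 111 and Tmem45b at 40952 ± 383 against 141 ± 93.4. Among peptide genes, Nmb was higher in DP (22287 ± 1034 against 9646 ± 831), while Tac1, the substance P precursor (Entrez 21333, chromosome 6, 7555071 to 7562973), was at 103342 ± 160 in DN against 10085 ± 518 in DP. Adcyap1, the PACAP precursor (Entrez 11516, chromosome 17, 93199422 to 93205489), was at 41625 ± 1484 in DN against 1278 ± 219. Markers of myelinating Schwann cells and of blood vessels were also far higher in DN, with Prx at 4726 ± 833 against 53.3 ± 5.04 and Cldn5 at 9028 ± 3669 against 73.9 ± 30. Markers of several cell types were thus high in DN.

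In this comparison 1645 genes were called (24.8%), 615 higher in DP and 1030 lower, with a median absolute log2 fold change of 2.05. Serpina11 (Entrez 380780) was at 1070 ± 77.3 in DP and at the floor in DN (0.473 ± 0.642), and Mrgpra3 (Entrez 233222, chromosome 7, 47588950 to 47601372) at 796 ± 50.2 against 2.8 ± 3.96, where reads may be shared with paralogs. The next largest toward DP were Ms4a3 (Entrez 170813; log2 fold change 9.05), Mrgprd (8.74), Tmem45b (Entrez 235135; 8.34), Otoa (8.22), Bcl2l14 (Entrez 66813; 8.17) and Cyp4f39 (Entrez 320997; 7.60), with limma BH-adjusted p from 2.15e-05 for Tmem45b to 0.000427 for Ms4a3. Toward DN they were Smoc2 (Entrez 64074; -7.99), Ctla2a (-7.52), Emcn (Entrez 59308; -7.50), Slco1a4 (Entrez 28250; -7.31), Vwf, the von Willebrand factor gene (Entrez 22371; -7.31), Ly6c1 (Entrez 17067; -7.11), Igf2 (-7.08) and Cldn19 (Entrez 242653; -7.03), with limma BH-adjusted p from 0.000114 for Ly6c1 to 0.00703 for Igf2. Ctla2a lost its call without DN replicate 2 (limma BH-adjusted p = 0.0698), and Igf2 without DN replicate 1 (0.0626) or without DN replicate 2 (0.061). The DN libraries of Ms4a3 were at 0 and 8.96, those of Bcl2l14 at 0.8 and 9.01, and the DP libraries of Smoc2 at 10.8 and 1.8. The log2 fold changes without DN replicate 1 and without DN replicate 2 were 7.97 and 9.50 for Mrgprd, 7.62 and 9.07 for Tmem45b, and 6.89 and 8.31 for Cyp4f39. For Ctla2a and Emcn they were -8.23 and -8.24 without DP replicate 1, and -6.80 and -6.76 without DP replicate 2. The share of calls higher in DP was 37.4% (48.2% under quantile normalization, 863 higher and 929 lower; 24% in the RPKM table, which adds lower genes and moves the median of all genes to -0.182).

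Of 21 Mrgprd nociceptor markers, 20 were higher in DP and 0 lower (camera BH-adjusted p = 7.96e-10; adjusted p = 0.406 with an estimated correlation). C-LTMR markers were also mostly higher in DP than in DN, 13 of 17, with 3 lower (camera BH-adjusted p = 0.00344, adjusted p = 0.58 with an estimated correlation), Fam19a4 and Ceacam10 (254 ± 41.6 against 6.08 ± 1.83) among those higher. The C-LTMR list shares Gfra2, Ret and Runx1 with the Mrgprd nociceptor list. Of 12 peptidergic markers, 11 were lower in DP and 1 higher (camera BH-adjusted p = 0.000104; adjusted p = 0.58 with an estimated correlation), with Gpx3 at 550 ± 204 against 13759 ± 2277 and the receptor gene Kit at 223 ± 37.3 against 5433 ± 11.9. Of 11 neuropeptide precursors, 7 were lower and 2 higher (camera BH-adjusted p = 0.0239; adjusted p = 0.788 with an estimated correlation; 0.44 in the RPKM table and 0.0712 without DN replicate 1). TRP channels gave 4 higher and 1 lower of 8 (camera BH-adjusted p = 0.0324; adjusted p = 0.58 with an estimated correlation; median 1.07, against -0.0456 with adjusted p = 0.274 in the RPKM table), the lower one being the capsaicin receptor gene Trpv1 (623 ± 84.4 against 4657 ± 1539). GABA, glycine, glutamate and acetylcholine receptors gave 8 higher and 1 lower of 14 (camera BH-adjusted p = 0.0324; adjusted p = 0.648 with an estimated correlation), but in the RPKM table, with more members, their median was -0.36 (BH-adjusted p = 0.999). Counts adjusted over the list alone were the same for every list of this comparison.

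Markers of non-neuronal cells and immediate early genes were higher in DN as sets. Of 18 satellite glia and Schwann cell markers, 17 were lower in DP (camera BH-adjusted p = 8.32e-07; adjusted p = 0.58 with an estimated correlation), including the myelin gene Ncmap (101 ± 17.6 against 7193 ± 34.8). Of 14 endothelial, pericyte and fibroblast markers, 13 were lower (camera BH-adjusted p = 1.09e-05; adjusted p = 0.58 with an estimated correlation). Of 22 immediate early, stress and injury genes, 19 were lower (camera BH-adjusted p = 1.71e-05; adjusted p = 0.747 with an estimated correlation), among them the nuclear receptor gene Nr4a2 (617 ± 5.4 against 5963 ± 736) and Btg2 (4526 ± 133 against 36891 ± 11896). Of 3 immune markers, S100a9 was higher in DP and Cd14 lower, and the call of S100a9 (log2 fold change 2.52) was lost without DP replicate 1 (limma BH-adjusted p = 0.147), without DP replicate 2 (0.183) or without DN replicate 1 (0.0701). Of 3 red blood cell genes, Bpgm was lower.

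Itch-related markers gave 3 higher and 0 lower of 4, and Mas-related receptors 2 and 0 of 3, both lists too short for camera. The other lists did not pass camera between DP and DN. Voltage-gated sodium channels gave 3 higher and 1 lower of 10 (BH-adjusted p = 0.597), with the nociceptor channel genes Scn11a at 50035 ± 2966 against 11889 ± 981 and Scn10a at 31583 ± 1067 against 8117 ± 1158. Voltage-gated calcium channels gave 3 and 1 of 7 (camera BH-adjusted p = 0.386), voltage-gated potassium channels 2 and 3 of 15 (0.887), leak and inward rectifier potassium channels 2 and 4 of 7 (0.679), and purinergic, acid-sensing, HCN and mechanosensitive channels 7 and 2 of 15 (0.203). Piezo2, listed as Fam38b, was at 7133 ± 816 in DP against 802 ± 153. Axon guidance genes gave 4 higher and 4 lower of 19 (camera BH-adjusted p = 0.695), while the RPKM table, with more members, gave a median of -1.51 (BH-adjusted p = 0.00388). Cadherins gave 3 and 2 of 6 (camera BH-adjusted p = 0.495), neurotrophic factor receptors 4 and 7 of 12 (0.535), sensory transcription factors 4 and 5 of 18 (0.616), RGS and G protein genes 11 and 3 of 31 (0.145; 0.0407 when rescaled to pan-sensory-neuron genes), and amine, opioid, prostaglandin and somatostatin receptors 3 and 2 of 5 (0.679). Myelinated neuron markers gave 1 and 2 of 9 (0.991) and pan-sensory-neuron genes 4 and 3 of 18 (0.268; 0.0357 in the RPKM table). Median and mean differed in sign for the myelinated markers (0.0165 and -0.5), the transcription factors (0.298 and -0.463) and the amine to somatostatin receptors (1.5 and -0.132). Ribosomal protein genes (median -0.186, camera BH-adjusted p = 0.116) and oxidative phosphorylation genes (-0.158, 0.162) held 0 called members. Both lists passed under quantile normalization (medians -0.195 and -0.177, BH-adjusted p = 0.0178 and 0.0156), and the ribosomal list also without DN replicate 1 (-0.321, BH-adjusted p = 0.0188).

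C-LTMR against DN sets the mechanoreceptors against the same remaining cells. Some C-LTMR markers were at low levels in DN: Cacna1i was at 4269 ± 913 against 5.32 ± 3.76, Ceacam10 at 4767 ± 209 against 6.08 ± 1.83, and Fam19a4 at 15912 ± 1644 against 26.5 ± 5.22. Mrgpra3, an itch receptor gene, was at 10271 ± 2198 in C-LTMR, 796 ± 50.2 in DP and 2.8 ± 3.96 in DN. Of the vessel genes, Ly6c1 was at 5.28 ± 2.7 against 9077 ± 3953 in DN and Cldn5 at 5.82 ± 1.94 against 9028 ± 3669. The mechanically gated channel gene Fam38b (Piezo2) was higher in C-LTMR than in DN (12948 ± 1834 against 802 ± 153).

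Here 1562 genes were called (23.6%), 594 higher in C-LTMR and 968 lower, with a median absolute log2 fold change of 2.11. The largest toward C-LTMR with a level above the floor in DN were Cacna1i (log2 fold change 9.52), Ceacam10 (9.42), Fam19a4 (9.19), Osta (8.37) and Wfdc2 (Entrez 67701; 8.24), with limma BH-adjusted p from 1.48e-06 for Fam19a4 to 2.51e-05 for Cacna1i. Cdh9 (1911 ± 298 against 2.14 ± 1.8) and C1ql4 (1531 ± 82 against 1.52 ± 0.446) were at the floor in DN. Toward DN, Slco1a4, Mgp, Emcn, Cxcl12 and Cd93 were at 3366 ± 1792, 5010 ± 1471, 3302 ± 1578, 4442 ± 1384 and 3836 ± 1506 in DN and at 0.541 ± 0.76, 1.59 ± 0.659, 1.55 ± 2.14, 2.13 ± 0.0946 and 2.11 ± 1.37 in C-LTMR. Igf2 was listed at about 0 in both C-LTMR libraries and at 1519 ± 29 in DN. The DN libraries of Cacna1i were at 2.66 and 7.98. Mrgpra3 in DP against C-LTMR (log2 fold change -3.67, limma BH-adjusted p = 0.0146) lost its call without DP replicate 1 (0.0654), without DP replicate 2 (0.0678), without C-LTMR replicate 1 (0.0962) and without C-LTMR replicate 2 (0.0713). The share of calls higher in C-LTMR was 38% (27.6% in the RPKM table; 47.8% under quantile normalization, 823 higher and 897 lower; 21% with values rescaled to pan-sensory-neuron genes, 368 higher and 1388 lower, with a median of all genes of -0.413).

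Of 17 C-LTMR markers, 14 were higher and 1 lower (camera BH-adjusted p = 8.32e-07; adjusted p = 0.406 with an estimated correlation). Mrgprd nociceptor markers were also higher in C-LTMR than in DN, 12 of 21, with 2 lower (camera BH-adjusted p = 0.000341, adjusted p = 0.425 with an estimated correlation), as for Tmem45b (23701 ± 1341 against 141 ± 93.4) and the GDNF family receptor gene Gfra2 (22464 ± 688 against 869 ± 357). Gfra2, Ret and Runx1 are in the C-LTMR list as well. Voltage-gated sodium channels gave 7 higher and 0 lower of 10 (camera BH-adjusted p = 0.000936; adjusted p = 0.648 with an estimated correlation), with Scn1a at 1612 ± 67.7 against 282 ± 46 and Scn8a at 2985 ± 378 against 591 ± 163. Pan-sensory-neuron genes gave 5 higher and 2 lower of 18 (camera BH-adjusted p = 0.0355; adjusted p = 0.822 with an estimated correlation), with the synaptotagmin gene Syt1 at 27325 ± 2448 against 6461 ± 998 and Gap43 lower, at 7884 ± 409 against 28781 ± 1798. That list did not pass with quantile normalization (BH-adjusted p = 0.112), in the RPKM table with the genes of the TMM-normalized table (0.0582), or without C-LTMR replicate 1 (0.0584) or DN replicate 2 (0.0792). Counts adjusted over the list alone were the same for every list of this comparison.

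Most measured peptide, glial, vessel and immediate early genes were lower in C-LTMR than in DN. Of 12 peptidergic markers, 10 were lower and 0 higher (camera BH-adjusted p = 0.000162; adjusted p = 0.58 with an estimated correlation), and of 11 neuropeptide precursors 7 and 0 (camera BH-adjusted p = 0.00395; adjusted p = 0.747 with an estimated correlation; 0.0988 in the RPKM table), with Adcyap1 at 567 ± 30.5 against 41625 ± 1484. Glial markers gave 17 lower of 18 (camera BH-adjusted p = 2.97e-06; adjusted p = 0.58 with an estimated correlation), with Prx at 28.7 ± 4.18 against 4726 ± 833. Endothelial, pericyte and fibroblast markers gave 13 lower and 1 higher of 14 (camera BH-adjusted p = 6.87e-06; adjusted p = 0.58 with an estimated correlation). Immediate early, stress and injury genes gave 20 lower and 0 higher of 22 (camera BH-adjusted p = 1.7e-08; adjusted p = 0.648 with an estimated correlation), with Nr4a2 at 296 ± 63.7 against 5963 ± 736. Ribosomal protein genes had a median of -0.389 and 0 called members of 51 (camera BH-adjusted p = 0.000162; adjusted p = 0.822 with an estimated correlation). Of 3 immune markers 3 were lower (S100a9, Lyz2 and Cd14), and of 3 red blood cell genes 2 were higher in C-LTMR than in DN, Alas2 among them. The log2 fold change of Alas2 was 2.43 without DN replicate 1 and 3.90 without DN replicate 2.

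Itch-related markers gave 1 higher and 0 lower of 4, and Mas-related receptors 2 and 0 of 3, both too short for camera. The other lists tested between C-LTMR and DN did not pass. Sensory transcription factors gave 7 higher and 5 lower of 18 (BH-adjusted p = 0.267; median 0.561 and mean -0.0185), with Pou4f2 at 4765 ± 301 against 56.5 ± 33.7 (log2 fold change 7.15 without DN replicate 1 and 5.87 without DN replicate 2) and Bcl11b at 92 ± 13.6 against 2152 ± 28.1. Purinergic, acid-sensing, HCN and mechanosensitive channels gave 6 and 3 of 15 (camera BH-adjusted p = 0.0621; 0.0318 in the RPKM table), and calcium channels 4 and 0 of 7 (0.0643; 0.0484 without DP replicate 2). Axon guidance genes gave 6 and 2 of 19 (camera BH-adjusted p = 0.0996), voltage-gated potassium channels 6 and 2 of 15 (0.162; 0.0169 in the RPKM table), leak and inward rectifier channels 2 and 3 of 7 (0.616), and TRP channels 2 and 1 of 8 (0.232). GABA, glycine, glutamate and acetylcholine receptors gave 7 and 4 of 14 (camera BH-adjusted p = 0.151), with Chrna4 at 1500 ± 291 against 29 ± 5.87. Amine, opioid, prostaglandin and somatostatin receptors gave 2 and 2 of 5 (camera BH-adjusted p = 0.535), cadherins 3 and 2 of 6 (0.386), neurotrophic factor receptors 3 and 5 of 12 (0.405), RGS and G protein genes 6 and 7 of 31 (0.789), and myelinated neuron markers 4 and 2 of 9 (0.386). Of 65 oxidative phosphorylation genes 0 were called (median -0.0243, camera BH-adjusted p = 0.675).

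**Figure D2:**
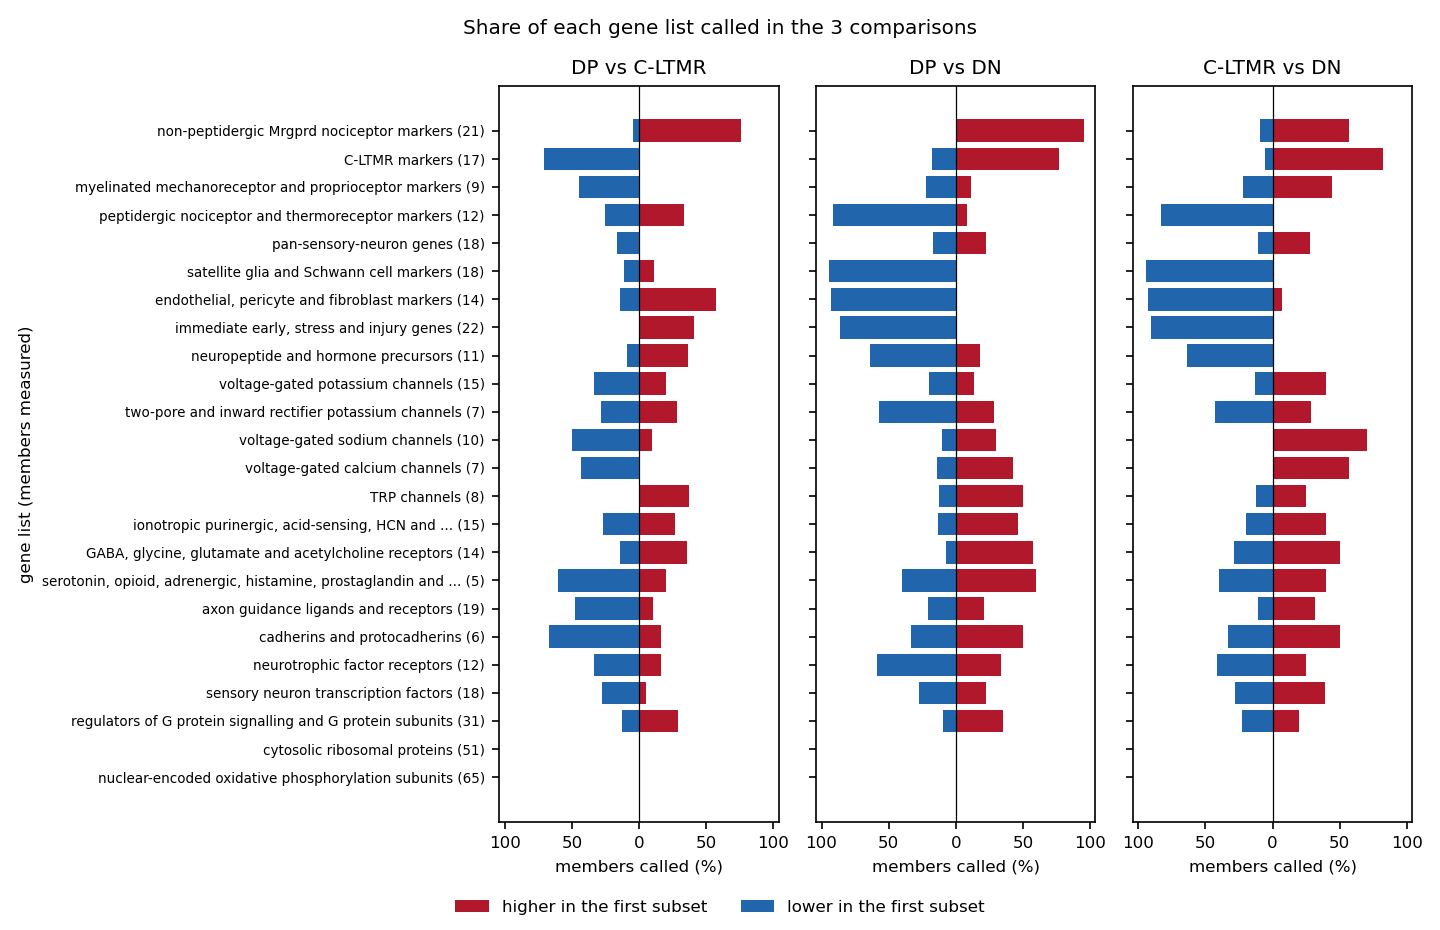
Percent of each list's measured members (number in brackets) that were called higher (red, right) or lower (blue, left) in the first subset of each comparison. Of 18 glial markers, 17 are lower in DP than in DN and 17 lower in C-LTMR than in DN, while 2 are lower in DP than in C-LTMR.

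The GINIP+ subsets shared much of their difference from DN. Against DN, 384 genes were higher in both DP and C-LTMR and 787 were lower in both. The balance depended on the scaling, with 610 and 728 under quantile normalization and 268 and 892 when rescaled to pan-sensory-neuron genes. Tmem45b, Grik1 and N28178 were among the genes higher in both, and Tac1, Adcyap1 and Prx among those lower in both. The log2 fold changes against DN correlated across genes with r = 0.831 (mean 0.727 and highest 0.739 in 100 simulated draws of unchanged groups), and their covariance was 1.89 against 0.0158 in the simulation, a difference of 1.87. Genes are not independent replicates. With the DN libraries split, an alternative added after the data were seen, DP against DN replicate 1 and C-LTMR against DN replicate 2 shared 359 genes higher and 742 lower (56.2 and 152 for independent lists), with r = 0.792. The other split shared 372 and 762 (55.7 and 148), with r = 0.828, so the overlap did not need a shared DN library. Across the splits, 50 and 30 genes were called in opposite directions. With all libraries, 34 genes were called in opposite directions, 15 higher in DP and lower in C-LTMR than in DN, and 19 the reverse. Among genes set apart in a subset from both others, 155 were enriched in DP, with Otoa, Mrgprd, Prkcq, Lpar3 and Agtr1a at the top, and 230 were depleted there. In C-LTMR, 173 were enriched, with Ceacam10, Osta, Th, Bmp15 and Cacna1i at the top, and 207 depleted (117 and 362 when rescaled to pan-sensory-neuron genes). In DN, 787 were enriched, with Smoc2, Ctla2a, Emcn, Slco1a4 and Vwf at the top, and 384 depleted. By definition these are the same genes as those lower, and those higher, in both GINIP+ subsets than in DN.

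**Figure D3:**
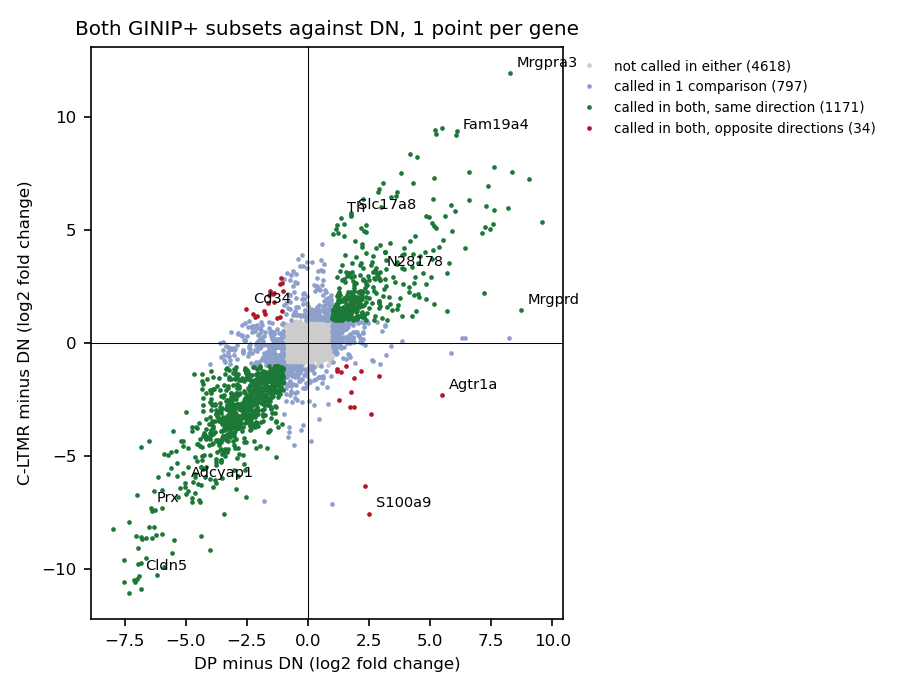
Log2 fold change of each of the 6620 genes in C-LTMR minus DN (vertical axis) against DP minus DN (horizontal axis), coloured by call. Green points are the 1171 genes called in the same direction in both comparisons and red points the 34 called in opposite directions, Agtr1a, S100a9 and Cd34 among them.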

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

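The test of myeloid cells by granule genes was written before its values were seen. All other tests of explanations in this part were chosen after the result was seen, and the test of non-neuronal cells in the DN gate was added after the result of the satellite glia test. The test of library scaling replaced an earlier count after rescaling to pan-sensory-neuron genes, which moved all genes toward the pattern and so could not have ended it. Its replacement used medians that were known by then, so its outcome was also set beforehand. The test of carry-over also replaced an earlier one after its outcome was known, and the test of satellite glia was then extended from DN to all 3 subsets.

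A difference between groups brought up 34 genes, which were higher than in DN in one GINIP+ subset and lower in the other and were also called between DP and C-LTMR. The call between DP and C-LTMR follows largely from opposite calls against the same DN libraries and adds no support. Serping1, a complement inhibitor gene outside the naming rule and chosen after its values were seen, was at 19323 ± 1832 in DP, 370 ± 54.3 in C-LTMR and 3256 ± 180 in DN. Cd34, chosen the same way, was at 503 ± 25.7, 8135 ± 1071 and 2984 ± 1105.

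Signals in data that the comparisons did not use came from genes listed only in the RPKM table, with values given as mean RPKM in DP, C-LTMR and DN. Of the 7545 such genes in the RPKM fit, 3801 (50.4%) were called in 1 or more comparisons, so a called gene is common there. Of 12 itch-related markers, 10 entered the fit and 10 were called, such as the histamine receptor gene Hrh1 at 0.447, 3.88 and 0.254. Of 19 immune cell markers, 12 entered and 12 were called, such as S100a8 at 67.5, 0.0745 and 11.2. Of 17 Mas-related receptor genes, 8 entered and 8 were called, such as Mrgprb5 at 19.7, 2.9 and 0.0822. Of 51 axon guidance genes, 40 entered and 37 were called, 30 of them lower in DP than in DN and 25 lower in C-LTMR than in DN, such as Robo4, a gene known from blood vessels, at 0.0457, 0.0042 and 5.31. Endothelial and glial markers moved the same way, with median log2 fold changes between DP and DN of -5.16 and -2.92 in the RPKM table.

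Some myeloid genes, S100a9, Ngp and Lyz2 among them, were present in DP and near 0 in C-LTMR, while Cd14 was not called between them. Expression of a few myeloid genes by DP neurons was examined with general leukocyte genes. Of 9, 7 were also called higher in DP than in C-LTMR, Tyrobp and Cd52 among them, but not Laptm5 or Coro1a. Against DN these 7 did not move alike. Srgn and Arhgdib were called lower in DP (log2 fold change -3.96 and -1.09), and Fcer1g and Ctss were not called. Cd53, Cd52 and Tyrobp were called higher (1.03, 1.7 and 1.32). The count against C-LTMR therefore does not settle this explanation. Carry-over of all non-neuronal cells alike was examined in DP against DN. Glial and vessel markers were already known to be high in DN, and S100a9 and Ngp to be higher in DP than in DN (log2 fold change 2.52 and 2.34). The median log2 fold change of 10 granule genes in the RPKM fit was 2.25 (SD 0.806), above that of the glial list (-2.92, SD 1.48) by 5.17 and above that of the endothelial list (-5.16, SD 2.11) by more. These granule genes thus did not share the ratio of these lists to DN, but both sides of the comparison were partly known beforehand. Elane, Cebpe and Mmp8 reached the RPKM minimum in both libraries only in DP, which favours a high ratio for them. A separate share of vessel cells is not excluded. Between DP and C-LTMR, 8 of 14 endothelial, pericyte and fibroblast markers were higher in DP and 2 lower, against 2 and 2 of 18 glial markers. Myeloid cells in the DP gate may be the source, since 10 of 12 neutrophil granule genes were above the RPKM minimum in both DP libraries and higher there than in both C-LTMR libraries, 9 of them called and Prtn3 not (1.13 against 0.671 RPKM). Whether such cells bind IB4 was not tested.

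Mrgpra3, an itch receptor gene, was high in C-LTMR. The highest other gene of its family there, Mrgpra2b, was at 3.75% of the RPKM of Mrgpra3. Reads of paralogs that were assigned to Mrgpra3 would leave the paralogs low too. This value therefore cannot decide whether such reads were the source. Mrgpra3 neurons in the C-LTMR gate may contribute, as Mrgprx1, which these neurons share, was higher in C-LTMR than in DP by a log2 fold change of 2.56 (limma BH-adjusted p = 0.00276). Mrgprx1 was itself low, at a mean of 6.0 RPKM in C-LTMR against 225 for Mrgpra3. Of the other genes looked at as partners of Mrgpra3, Osmr and Hrh1 were also called higher in C-LTMR than in DP in the RPKM fit. Osmr was not called between C-LTMR and DN. Mrgprb5 and Mrgprb4 were higher in DP than in C-LTMR. Expression by the C-LTMRs themselves stays open and was not tested.

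Immediate early genes were high in DN. Scaling of the libraries moves all genes alike, so by itself it would not set the members apart from the other genes. In C-LTMR against DN the median log2 fold change of the 22 measured members minus that of all genes was -3.22 (SD of the members 1.21). Both medians, -3.21 for the list and 0.011 for all genes, were already known. The difference therefore restates the pattern and is not a separate test. Satellite glia in the DN gate cannot be told apart from other sources: from DN replicate 1 to replicate 2 the members rose by a median log2 difference of 0.541, which is -0.632 relative to the satellite glia genes (SD of the members 0.357), with 19 of 20 members higher there and 19 of 20 in C-LTMR, while in DP they rose by only 0.0249 (14 of 20) against 0.568 for these genes, and each subset has only 1 pair of libraries. The same pair leaves non-neuronal cells in the DN gate in general open, as 0.541 lay between the differences of pan-sensory-neuron genes (-0.359) and endothelial markers (0.849). A response of DN neurons to dissociation or sorting stays open and was not tested.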

How the results depend on the processing

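Rescaling to the pan-sensory-neuron genes, the RPKM table limited to the genes of the TMM-normalized table and the split of the DN libraries were chosen after seeing the data. With no filter and with a filter of at least 50 in at least 2 libraries 0 genes were removed, so neither could change a result. Across the other alternatives, 151 counts stayed within 1.5 times the reported count and 30 moved further. These counts are not separate, since the DN-enriched and DN-depleted sets together are the overlap against DN. Of the list tests, 1078 kept the direction of the test and side of the threshold, 46 lost and 26 gained significance, and 2 reversed. Of the named gene results, 5041 kept both, 120 lost and 7 gained their call, and 0 reversed. Of the 120, 46 were lost with limma treat.

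In the RPKM table the called genes numbered 2168 (DP vs C-LTMR), 4687 (DP vs DN) and 4491 (C-LTMR vs DN), with 353 DP-enriched, 662 DP-depleted, 456 C-LTMR-enriched, 546 C-LTMR-depleted, 2742 DN-enriched and 673 DN-depleted genes and 3415 in the overlap against DN. More genes were tested there, and limited to the 6620 genes it called 846, 1637 and 1559. The test of 2 lists reversed between DP and DN, with medians of -0.357 for GABA, glycine, glutamate and acetylcholine receptors and -1.51 for axon guidance genes, where the RPKM table measures more members. The median of TRP channels turned as well, from 1.07 to -0.0456, while the direction of its test did not. With no fold change criterion the counts were 2296, 4174 and 4053, the sets 673, 590, 584, 563, 1545 and 1443 in the order above, and the overlap 2988, as a wider criterion gives. With limma treat against a log2 fold change of 1, 399 genes were called for DP vs C-LTMR, with 77 DP-enriched, 106 DP-depleted, 94 C-LTMR-enriched, 69 C-LTMR-depleted and 222 DN-depleted genes and an overlap of 761, as a stricter criterion gives. Quantile normalization gave 610 DN-depleted genes and rescaling to the pan-sensory-neuron genes 362 C-LTMR-depleted genes; the cause was not tested. With values rescaled to the pan-sensory-neuron genes 15 list tests gained significance, with BH-adjusted p from 0.00112 (calcium channels, C-LTMR vs DN) to 0.0407. With an estimated inter-gene correlation 0 list tests passed, where 6 were under 0.05 before adjustment.

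With 1 library left out, the counts ranged from 753 to 849 (DP vs C-LTMR), 1553 to 1762 (DP vs DN) and 1450 to 1679 (C-LTMR vs DN). The sets, the overlap and the number of list tests that passed also varied, and 1 subset then held a single library. A lone library is assumed to vary like the other groups. With a replicate block the counts were 858, 1647 and 1561 and 25 of the 27 list tests still passed, those of the sodium and TRP channels between DP and C-LTMR being lost. Of the reported calls, 842 of 843, 1645 of 1645 and 1561 of 1562 were shared, and no call of a named gene changed. With separate DN libraries for DP and for C-LTMR the overlap was 1101 and 1134 genes, and that alternative gives no other result. The fit of only the 4 libraries compared gives no sets or overlap. Count models (edgeR and DESeq2) were not run, since whole reads could not be recovered. At this depth a value under about 3 normalized counts cannot be told from 0.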

Other observations

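Some genes listed only in the RPKM table differed between subsets. Nts, the neurotensin precursor gene, was at 12.3 ± 7.48 RPKM in DP (SD, n = 2) against 1.63 ± 1.52 in C-LTMR and 2.01 ± 0.609 in DN (DP over C-LTMR, limma BH-adjusted p = 0.0185), and its DP libraries were at 17.6 and 7.02. The histamine receptor gene Hrh1 was higher in C-LTMR than in DP (log2 fold change 2.86 on the RPKM scale, limma BH-adjusted p = 0.000135), and the netrin receptor gene Unc5a was at 2.71 ± 0.172 RPKM in C-LTMR against 0.455 ± 0.0608 in DP and 0.253 ± 0.0631 in DN. Ntn5, a netrin gene, was at 16.4 ± 1.14 RPKM in DN against 0.466 ± 0.00772 in DP and 0.177 ± 0.0714 in C-LTMR. These genes were chosen after their values were seen.

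Satellite glia genes were higher in replicate 2 than in replicate 1 of every subset, 5 of 5 genes in each, with median log2 differences of 0.568 in DP, 1.09 in C-LTMR and 1.17 in DN. Pan-sensory-neuron genes differed by a median of 0.00614 in DP, -0.0336 in C-LTMR and -0.359 in DN, where 0 of 18 were higher in replicate 2. Both sets were looked at after the data were seen.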
